A study of Mus musculus with 18 samples.

How the data were processed

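All values came from tables deposited with the series, and no reads were processed here. Per the submitters' processing notes, reads were aligned with BWA, and SAMtools and bedtools were used for the H3K4me3 tables. The notes give no versions. Builds were mm10 and, for 3 further DMC1 lists, mm9. Per the labels' protocols, DMC1 libraries came from snap-frozen testes by single-stranded DNA sequencing, and H3K4me3 libraries from fixed whole adult testis. The hotspot caller and its filters are not given in the sources used here. The B6/B6 DMC1 map is listed for the series as a whole, as a re-analysis of a library of other submitters.

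The DMC1 heat of a hotspot is a relative signal made by the authors, with its definition not given in the sources used here. The B6 share of DMC1 reads is a fraction deposited by the authors from 0 to 1, without the number of informative reads, so no interval that needs this number was made. The allele column of the infertile, reciprocal and rescue F1 maps was made by the authors. Per the file headers, H3K4me3 counts are numbers of ChIP or input fragments that overlap each 1 kb bin centred on a hotspot. Per the file headers, the enrichment is a maximum-likelihood ratio to local background coverage with a minimum of 0. The deposited p-value is from a likelihood ratio test against an enrichment of 0, per the file headers. Per the file headers, 1 further column marks bins that overlap an H3K4me3 peak likely to be PRDM9-independent. The F1 tables also hold the B6 share of H3K4me3 as a fraction estimated by the authors, with the number of informative reads after background subtraction. Per the labels, the B6/B6 table used the input library of Hum/Hum males. Each table has its own scale, so levels were compared within tables and as ratios.

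Computation here used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 with GENCODE M21 gene models. The samples, comparisons and most alternatives were fixed before the data were examined. Autosomes were used unless the X chromosome is named. In the B6/Hum map the chromosome coded as 20 was taken as X, because 60.1% of its 1042 centres lay within 1 kb of X bins of the Hum/Hum table and at most 2.40% within 1 kb of bins of any autosome. Every autosomal centre of the 5 maps with an H3K4me3 table had a bin with the identical centre. No position lay beyond the end of its mm10 chromosome.

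A hotspot counted as shared when a centre of the other map lay within 1000 bp. Chance came from 1000 circular shifts of the second map along each chromosome, 100 shifts for pairs that include a PWD hybrid map, and 200 for transcription starts. Shares carry Wilson 95% intervals, and medians, ratios and correlations carry intervals from 200 bootstrap draws of 5 Mb blocks. Hotspots of hybrid maps were assigned by the homozygous map they matched. Symmetric means a B6 share from 0.1 to 0.9, and H3K4me3 B6 shares were used with at least 10 informative reads. Random lists numbered 10000. Promoters are 1000 bp around 90262 transcription starts of protein-coding transcripts. List genes were extended by 2000 bp. Ratios of ChIP to input sums were made per replicate, without bins whose input exceeded 10 times the median, and replicates of 2 crosses were compared by an exact permutation test of the difference in means.

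Named genes are those at the 3 hottest hotspots of each map, the 5 hottest found in only 1 or in both maps of a pair, the 3 hottest of each symmetry class, the 3 highest H3K4me3 enrichments and members of 5 fixed lists. A hotspot outside genes was given the nearest gene and its distance. Some genes that meet this rule are not reported here. Top6bl stands under Gm960 in GENCODE M21.

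The matching code was tested on a simulated second map against the B6/B6 map with n = 16974 hotspots. With a true shared share of 0, 5, 30 and 70% it found 1.45, 6.36, 30.7 and 70.2%, and after removal of chance 0.0376, 5.01, 29.7 and 69.7%.

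The 4 input libraries and the PWD spleen genomic DNA were not analysed here on their own. X hotspots of the other DMC1 maps were not analysed here. The DMC1 maps have 1 library per genotype, so genotypes were not tested against each other on DMC1.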

Results

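The data mapped meiotic DNA double-strand breaks and a histone mark of the break machinery in mouse testis. PRDM9 is the zinc-finger protein that places H3K4me3 at recombination hotspots, and DMC1 is the strand-exchange protein bound to the single-stranded DNA of the breaks. DMC1 ChIP-seq gave 9 autosomal hotspot maps, each from 1 library, so no DMC1 map had a replicate. Inbred B6 males carried the B6/B6, B6/Hum or Hum/Hum genotype at Prdm9, where Hum is the humanized allele, and a PWD/PWD map came from the PWD strain. Hybrid males gave 5 maps. The infertile F1 map came from sons of PWD mothers and B6 fathers with the PWD and B6 alleles, and the reciprocal F1 map from the opposite cross. The rescue F1 map came from sons of PWD mothers carrying the PWD and Hum alleles, the Hum/PWD F1 map from the opposite cross, and the last hybrid map from a B6 by CAST cross. H3K4me3 counts covered 1 kb bins centred on the hotspots of 5 of these maps. The 3 F1 tables held 2 biological replicates each, and the B6/B6 and Hum/Hum tables held pseudoreplicates of 1 library. Usable depth was 40 to 50 M read pairs of 51 bp per F1 replicate and 70 to 80 M per B6 library, per the labels' protocols. The males of the 8 DMC1 samples of this series were about 10 weeks old. The B6/B6 map was a re-analysis of a library of other submitters, and no age is given for it here. All coordinates below are mm10.

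How many hotspots were called in each map came first. The infertile F1 map was the longest, with 23554 autosomal hotspots or 9.56 per Mb. The PWD/PWD map held 21103, the Hum/PWD F1 map 20623, the B6 by CAST map 18740, the reciprocal F1 map 17516, the B6/B6 map 16974, the B6/Hum map 16163, the Hum/Hum map 15515 and the rescue F1 map 15019. The lowest heat called was 4 in the infertile, 5.9 in the PWD/PWD, 6.4 in the reciprocal, 10.9 in the Hum/Hum and 13.7 in the rescue map. Longer lists thus mostly reached weaker hotspots, so the counts do not show how many hotspots a genotype used. Autosomal heat, the deposited DMC1 signal of a hotspot, summed to between 1.39e+06 and 1.496e+06 in every map, so heat cannot compare the total number of breaks between maps. Median heat was 25.4 in the infertile map, 37.7 in the reciprocal map, 57.8 in the rescue map and 34.5 in the Hum/PWD map. With sums so alike, a longer list must have less heat per hotspot on average. Median heat thus does not compare the strength of hotspots between maps. The hottest 10% of hotspots carried 44.2% of the heat in the infertile, 42.4% in the reciprocal, 41.1% in the Hum/PWD, 35.5% in the rescue and 35.1% in the B6/B6 map. These are values of single libraries and were not tested.

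Whether the humanized zinc fingers moved the hotspots of B6 mice was asked next. The B6/B6 and Hum/Hum maps were almost separate. Of 16974 B6/B6 hotspots 364 lay within 1 kb of a Hum/Hum hotspot, 2.14% with a 95% Wilson interval of 1.94 to 2.37%. Shifting the Hum/Hum map along each chromosome 1000 times gave 1.30% on average and never more than 1.72%. The overlap was 1.20% with a 500 bp limit and 3.99% with 2000 bp. The hottest B6/B6 hotspots missing from the Hum/Hum map lay 6667 bp from Asxl2 (intergenic, chr12:3513519, heat 674.1), in an intron of Fat4 (chr3:38905074, 670) and in a coding exon of the receptor gene Notch2 (chr3:98137362, 643.3). Among the hottest Hum/Hum hotspots missing from the B6/B6 map were sites 4312 bp from Phtf2 (intergenic, chr5:20754351, 1016.7), in an intron of Gm47771 (chr10:17565281, 841.4) and in an intron of Cfap54 (chr10:93007643, 776.9). Wilson intervals here and below cover the counting of hotspots only.

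Some of the shared hotspots were of another kind. A hotspot in a coding exon of Gm10800 (chr2:98667186) was present in all 9 maps, with heat from 709.6 in the infertile map to 3024.8 in the B6 by CAST map. The input library held at least 3140 times the median bin count at this place in every H3K4me3 table. In total 36 sites were hotspots in all 9 maps, and 19 of them, including an intron of Gm33838 on chromosome 9, had input above 10 times the median in every table. An intron of Map4k3 (chr17:80626053) and an intron of Zdhhc19 (chr16:32540273) were hotspots in all maps with ordinary input. Such high-input sites are left out of the gene examples below.

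Which allele set the hotspots of heterozygous B6/Hum males was asked next. The Hum allele set most of them. Of 16163 autosomal hotspots 11175, or 69.1% (68.4 to 69.8%), matched the Hum/Hum map only and 4277, or 26.5% (25.8 to 27.1%), matched the B6/B6 map only, a ratio of 2.61. Hotspots of Hum/Hum type carried 77.5% of the heat and those of B6/B6 type 19.0%, with median heats of 52.4 and 37.7. Both maps held 314 of the hotspots and neither map held 397. Of the Hum/Hum hotspots 74.1% were found in the B6/Hum map, against 27.1% of the B6/B6 hotspots. The hottest B6/Hum hotspots not present in the Hum/Hum map lay in an intron of Ankfn1 (chr11:89611929, heat 740.8) and 209725 bp from Cmpk2 (chr12:26689562, 680.6). Across 11489 hotspots shared by the B6/Hum and Hum/Hum maps, within 1 pair of libraries, heat had a Spearman rho of 0.916, and across 4591 shared with the B6/B6 map a rho of 0.644. Hotspots are not independent replicates and no p-value is given. The B6/B6 map came from a library of other submitters. Effects of allele and of library source thus cannot be told apart in these comparisons.

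The X chromosome could be read in the B6/Hum map alone. It held 1042 X hotspots, 6.09 per Mb against 6.56 on the autosomes. X hotspots were hotter, with a median heat of 55.35 against 46.3, a ratio of 1.20 (bootstrap interval 1.04 to 1.31). They carried 9.79% of the heat with 6.06% of the hotspots. The hottest X hotspot lay 46395 bp from Bex3 (intergenic, chrX:136318373), with heat 1513.

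The PWD and B6 alleles were compared next. Of 21103 PWD/PWD hotspots 459, or 2.18% (1.99 to 2.38%), were shared with the B6/B6 map, against 1.42% on average and 1.75% at most after shifting. It was 1.22% within 500 bp and 3.94% within 2000 bp. The hottest PWD/PWD hotspots absent from the B6/B6 map lay in an intron of the transcription factor gene Klf5 (chr14:99308166, heat 651.5), 10186 bp from Akr1b3 (intergenic, chr6:34327664, 632.8), in an intron of Mastl (chr2:23151469, 632.3) and in a coding exon of Smap1 (chr1:23848466, 609.9). The PWD/PWD map had more in common with the B6 by CAST map. Of the PWD/PWD hotspots 11.4% were found there, 7.30 times the chance value of 1.56%. The CAST cross also held 19.8% of the B6/B6 hotspots and 39.6% of their heat. Across 3359 CAST-map hotspots shared with the B6/B6 map, heat had a Spearman rho of -0.0445 (bootstrap interval -0.0765 to -0.00684).

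The next question was which parental allele set the hotspots of the PWD hybrids. With the B6 allele opposite, PWD-type hotspots led. In the infertile map 40.4% of hotspots matched the PWD/PWD map only and 28.2% the B6/B6 map only, and in the reciprocal map the shares were 40.0% and 32.96%. With the Hum allele opposite, Hum-type hotspots led. In the rescue map 52.4% matched the Hum/Hum map only and 24.5% the PWD/PWD map only, and in the Hum/PWD map 48.3% and 28.4%. The ratio of non-PWD to PWD hotspots was thus 0.698 in the infertile, 0.824 in the reciprocal, 2.14 in the rescue and 1.70 in the Hum/PWD map. By heat, PWD-type hotspots carried 37.9% in the infertile map and 23.2% in the rescue map.

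**Figure D1:**
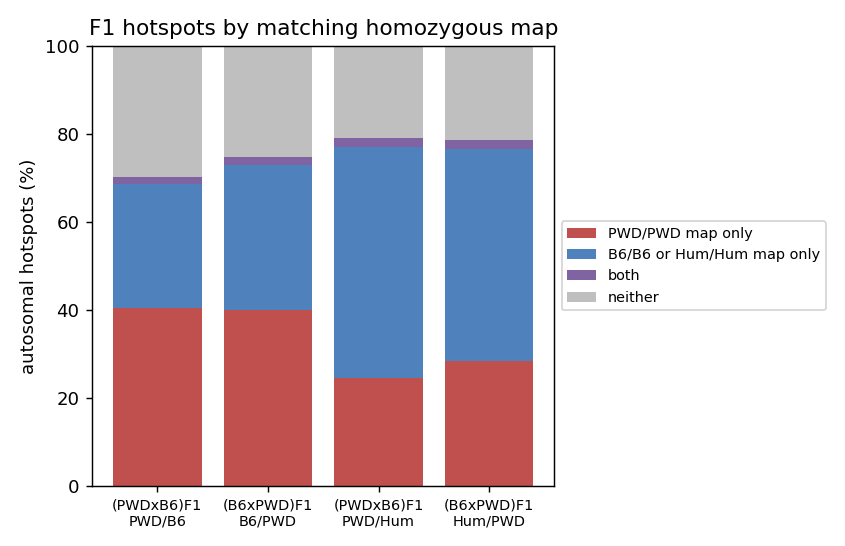
Share of autosomal hotspots of each PWD hybrid map that matched the PWD/PWD map only, the other allele's map only, both or neither, within 1 kb.

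A large class of hybrid hotspots matched neither homozygous map, with shares of 29.8% in the infertile, 25.3% in the reciprocal, 20.8% in the rescue and 21.5% in the Hum/PWD map. The order of the infertile and reciprocal maps turned in the hotter 0.5 of hotspots, with 36.3% and 39.3%, and by heat, with 30.4% and 32.1%. The authors' own allele column left fewer unassigned, 19.7% in the infertile, 10.9% in the reciprocal and 11.7% in the rescue map. The unassigned class differed between the reciprocal crosses. In the infertile map 44.3% (42.9 to 45.7%) of the 4634 unassigned hotspots lay within 1 kb of a protein-coding transcription start, and 54.9% sat in bins flagged as PRDM9-independent H3K4me3. In the reciprocal map 12.1% of 1904 lay near a start and 17.1% in such bins, and in the rescue map 7.48% of 1752 and 14.6%. Of the 9521 infertile-map hotspots matching the PWD/PWD map only, the authors' column also gave PWD for 8780.

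How many homozygous hotspots were lost in hybrids was asked next. PWD hotspots were lost most where the Hum allele was present. Of the 21103 PWD/PWD hotspots 46.9% were found in the infertile map, 34.7% in the reciprocal, 29.6% in the Hum/PWD and 19.0% in the rescue map. Of the B6/B6 hotspots 41.3% were found in the infertile and 35.8% in the reciprocal map. Of the Hum/Hum hotspots 52.9% were found in the rescue and 66.6% in the Hum/PWD map. Hot sites were kept more often than cold ones. In the hottest 25% of the PWD/PWD map 92.8% were found in the infertile and 50.5% in the rescue map, and in the coldest 25% 17.2% and 5.84%. In the hottest 25% of the Hum/Hum map 98.2% were found in the rescue map. The length of each hybrid map sets part of these shares. In the hottest 15019 hotspots of each hybrid map, the infertile map held 31.0% of the PWD/PWD and 28.8% of the B6/B6 hotspots and the reciprocal map 29.4% and 30.8%. The Hum/PWD map then held 50.8% of the Hum/Hum hotspots, so the order of the crosses turned for B6/B6 and Hum/Hum hotspots.

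Whether the direction of the cross changed the hotspots was asked by pairing maps with the same alleles. The infertile and reciprocal maps used nearly the same hot sites. Of the 17516 reciprocal hotspots 97.1% were in the infertile map, and across 17028 shared hotspots within this 1 pair of libraries heat had a Spearman rho of 0.957. Among the hottest shared sites were an intron of Sorcs1 (chr19:50170269, heat 845.5 in the infertile and 1019.6 in the reciprocal map), a site 47823 bp from the neurokinin receptor gene Tacr3 (intergenic, chr3:134982402, 702.7 and 917.6) and an intron of the hair-cell channel gene Tmc1 (chr19:20796490, 648.6 and 839.6). The 6526 hotspots found only in the infertile map were weak, with a median heat of 9.2 and 4.61% of the heat, and 31.7% (30.6 to 32.9%) of them lay near a transcription start. The rescue and Hum/PWD maps shared 14403 hotspots with a rho of 0.928, and the 6223 sites found only in the Hum/PWD map had a median heat of 13.8 and 6.78% of the heat, and 4.18% of them lay near a start.

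Replacing the B6 by the Hum allele in the same cross changed the hot sites. The infertile and rescue maps shared 5186 hotspots, with a rho of 0.795. Hot in the infertile map and absent from the rescue map were the site near Tacr3 and the intron of Tmc1. Hot in the rescue map and absent from the infertile map were an intron of Gm16090 (chr18:20641478, 949.9), the site near Phtf2 (chr5:20754332, 933.2), the intron of Cfap54 (927.5) and an intron of the histone demethylase gene Kdm3b (chr18:34810484, 835.9). An intron of Zfc3h1 (chr10:115417932) was hot in both, with heat 687.3 and 792.5.

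Whether breaks fell on both parental chromosomes was asked with the share of reads from the B6 chromosome. A hotspot was called symmetric when this B6 share lay from 0.1 to 0.9. The reciprocal map had the fewest symmetric hotspots, 45.3% (44.5 to 46.1%). The infertile map had 57.3% (56.6 to 58.0%), the rescue map 59.8% (58.98 to 60.7%), the Hum/PWD map 59.8% (59.1 to 60.6%) and the B6 by CAST map 71.2% (70.5 to 71.9%). By heat the 2 maps with the PWD and B6 alleles stood lower. Symmetric hotspots carried 34.3% of the heat in the infertile and 27.2% in the reciprocal map, against 53.6% in the rescue, 51.8% in the Hum/PWD and 51.2% in the CAST map. The asymmetric remainder leaned to the B6 chromosome in Hum hybrids, with 27.2% above 0.9 and 13.0% below 0.1 in the rescue map, and was even in the infertile map, with 22.0% and 20.7%. With limits of 0.3 and 0.7 the symmetric shares were 36.4% in the infertile, 26.9% in the reciprocal and 37.5% in the rescue map. H3K4me3 reads gave symmetric shares of 46.4% in 7602 reciprocal bins, 55.3% in 12380 infertile bins and 63.3% in 9216 rescue bins. Across hotspots of 1 pair of libraries the B6 shares by DMC1 and by H3K4me3 had a rho of 0.892 in the infertile, 0.888 in the reciprocal and 0.868 in the rescue cross.

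**Figure D2:**
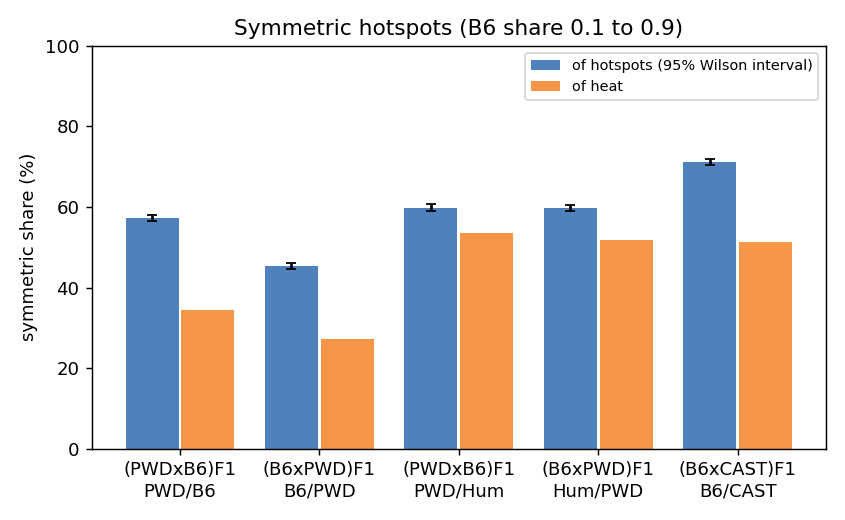
Symmetric share of each hybrid map by number of hotspots and by heat. Bars by number carry the counting interval.

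Some of the most one-sided hot sites were shared between crosses. The intron of Sorcs1 had a B6 share of 0.996 in the infertile and 0.994 in the reciprocal map, and the site near Tacr3 had 0.005 in both. The Tacr3 site was also among the hottest one-sided sites of the CAST cross, with heat 608.1 and a B6 share of 0.007, as was a site 329839 bp from Vgll3 (intergenic, chr16:66196207, 614.6, share 0.011). In the rescue map one-sided hot sites included an intron of the relaxin receptor gene Rxfp1 (chr3:79668803, 794.8, share 0.003) and an intron of Mllt3 (chr4:88017097, 786.3, share 0.994). Balanced and hot were the intron of Ankfn1 in the infertile map (566.2, share 0.515) and the intron of Cfap54 in the rescue map (share 0.419).

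Which allele caused the lean was asked by origin. PWD-type hotspots lay more on the B6 chromosome and B6-type hotspots more on the PWD chromosome. The median B6 share was 0.600 at PWD-type and 0.455 at B6-type hotspots of the infertile map, and 0.667 and 0.424 in the reciprocal map. Hum-type hotspots had medians of 0.538 in the rescue and 0.517 in the Hum/PWD map, where PWD-type hotspots had 0.643 and 0.526. The one-sided part of Hum-type hotspots lay mostly on the B6 chromosome. In the rescue map 21.5% lay above 0.9 and 3.84% below 0.1, and in the Hum/PWD map 22.0% and 3.76%. The matching itself favours this lean. The Hum/Hum map came from B6 males, so Hum sites found only on the PWD chromosome could not match it. By the authors' column, 19.9% of Hum hotspots of the rescue map lay above 0.9 and 12.3% below 0.1. By means in place of medians the difference between PWD-type and Hum-type hotspots fell to 0.0427 in the rescue map and turned to -0.0197 in the Hum/PWD map. Hotspots of neither type were nearly all one-sided in the reciprocal map, where 4.47% were symmetric, 45.8% lay below 0.1 and 49.8% above 0.9. The matching favours this as well. A site used on both chromosomes can be used in the allele's own strain too, and then matches a homozygous map. In the infertile map 31.2% of this class were symmetric. PWD sites found only on the B6 chromosome could not match the PWD/PWD map, nor B6 sites found only on the PWD chromosome the B6/B6 map. The matching thus narrows the gap between PWD-type and B6-type hotspots. By the authors' column this gap was wider, 0.348 at B6 and 0.667 at PWD hotspots of the infertile map and 0.239 and 0.765 in the reciprocal map. In the rescue map that column gave 0.500 at Hum and 0.712 at PWD hotspots. In the CAST cross B6-type hotspots had a median B6 share of 0.231.

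Asymmetric hotspots were hotter than symmetric hotspots in every hybrid. The ratio of median heat was 3.25 (bootstrap interval 3.10 to 3.45) in the infertile map, 2.30 (2.17 to 2.42) in the reciprocal, 1.42 (1.37 to 1.49) in the rescue, 1.61 (1.53 to 1.69) in the Hum/PWD and 3.61 (3.47 to 3.81) in the CAST map. In the infertile map the medians were 60.5 and 18.6. In the hotter 0.5 of the hotspots the ratio was 1.87 in the infertile, 1.78 in the reciprocal, 1.11 in the rescue, 1.12 in the Hum/PWD and 1.48 in the CAST map. With symmetry taken from 0.3 to 0.7 the excess ended in the Hum hybrids, with ratios of 0.960 in the rescue and 0.999 in the Hum/PWD map. The observed median of asymmetric hotspots exceeded all of 10000 random draws of as many hotspots in each map. These draws treat hotspots of the same library as independent, so they describe each map and are not a test. Heat per unit of H3K4me3 was also higher at asymmetric hotspots, by a ratio of 2.33 (2.22 to 2.43) in the reciprocal, 1.72 (1.67 to 1.76) in the infertile and 1.52 (1.49 to 1.57) in the rescue cross. These ratios used only bins with a deposited p-value below 0.05 that were not flagged as PRDM9-independent. This left 6877 of 15133 reciprocal, 14740 of 21059 infertile and 10418 of 12753 rescue hotspots with a B6 share.

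By heat, chromosome 19 stood lowest in the PWD hybrids. Chromosome 19 had the smallest symmetric share of heat in the infertile (28.4%), reciprocal (18.9%), rescue (49.5%) and Hum/PWD (45.1%) maps. In the rescue map chromosome 4 was level with it at 49.5%. Chromosome 1 had the largest in the infertile (42.5%) and reciprocal (36.5%) maps. By number the lowest in the infertile map was chromosome 8 with 52.1%, and in the CAST map chromosome 3 was lowest by heat with 42.9%. Hotspot density in the infertile map ran from 8.02 per Mb on chromosome 14 to 13.4 on chromosome 19, and in the PWD/PWD map it peaked on chromosome 11 with 10.3.

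H3K4me3 at hotspots was asked next, first within each table. Leaving out PRDM9-independent bins, median enrichment over background was 0.863 in the rescue, 0.816 in the infertile, 0.808 in the Hum/Hum, 0.380 in the B6/B6 and 0.372 in the reciprocal table. The share of bins with a deposited p-value below 0.05 was 87.1%, 81.1%, 88.7%, 64.4% and 45.8% in the same order. Below 0.001 the reciprocal share was 30.4%. The infertile table stood apart in PRDM9-independent bins. These made up 16.1% of its autosomal bins with a median enrichment of 14.2, against 7.24% and 1.46 in the reciprocal and 8.58% and 2.85 in the rescue table. They took 82.3 ± 0.874% (mean ± SD, n = 2) of the ChIP fragments in hotspot bins of the infertile males, 36.3 ± 1.07% in reciprocal and 29.2 ± 0.472% in rescue males. The exact permutation p-value for infertile against rescue was 0.333, the smallest that 2 against 2 samples can give. Tables were scaled separately and each covers its own hotspot list.

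**Figure D3:**
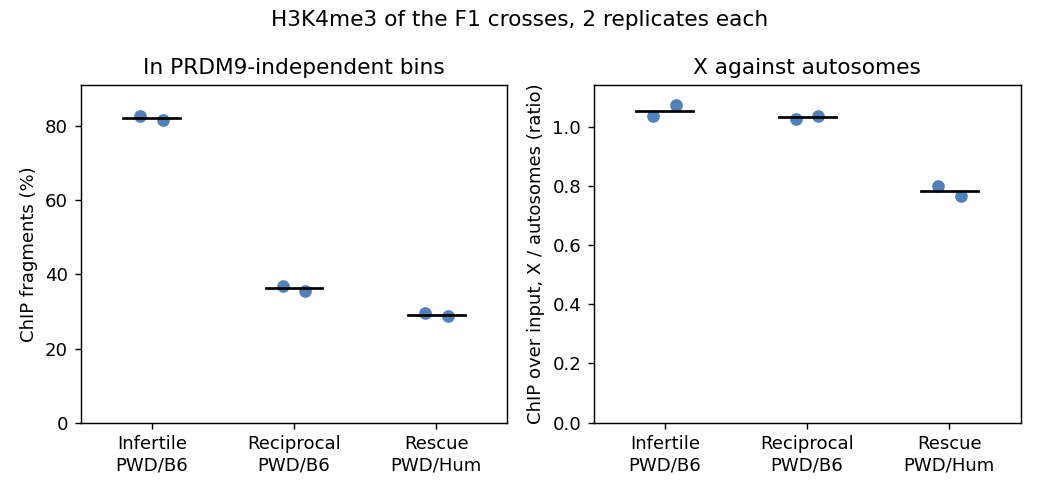
H3K4me3 of the F1 crosses by replicate. Left, share of hotspot-bin ChIP fragments in PRDM9-independent bins, and right, ChIP over input on the X chromosome relative to autosomes.

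H3K4me3 in X hotspot bins, relative to autosomal ones, had a lower ratio in both rescue replicates than in both infertile replicates. ChIP over input on X relative to autosomes was 1.04 and 1.07 in the infertile replicates, 1.03 and 1.04 in the reciprocal and 0.799 and 0.767 in the rescue replicates, with an exact p of 0.333 for infertile against rescue. Each cross has its own X bins, so these are not values of the same sites. Hotspots of the non-PWD allele had more H3K4me3 than PWD-type hotspots, with mean ratios of 1.24 in rescue, 1.13 in infertile and 1.08 in reciprocal males. Bins with input above 10 times the median were left out of these ratios, a choice made after the data were seen. With them kept, the reciprocal X ratio was 0.990.

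DMC1 heat rose with H3K4me3 at the same hotspots. Across hotspots within 1 pair of libraries the Spearman rho was 0.765 in the infertile, 0.717 in the Hum/Hum, 0.707 in the B6/B6, 0.670 in the rescue and 0.658 in the reciprocal cross. With PRDM9-independent bins kept it fell to 0.461 in the infertile and to 0.621 in the rescue cross. In bins with p below 0.05 only, the reciprocal rho was 0.412. Outside PRDM9-independent bins, the highest enrichment of the infertile table was 18.97 in an intron of 1700042D02Rik (chr9:49051675), and a coding exon of the spermatogenesis gene Rnf17 (chr14:56485160) had 17.9.

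How often hotspots lay at promoters separated the infertile and PWD/PWD maps from the others. Within 1 kb of a protein-coding transcription start lay 12.4% (11.999 to 12.8%) of infertile-map hotspots, 3.15 times the value after shifting, and 7.71% (7.36 to 8.08%) of PWD/PWD hotspots, 1.95 times. The other 7 maps ranged from 4.22% in the CAST cross to 4.90% in the reciprocal map, 1.07 to 1.24 times the shifted value. In the hottest 15019 hotspots of each map the ratio was 1.98 in the infertile and 1.53 in the PWD/PWD map, and within 2500 bp it was 2.08 and 1.58. For promoters the cut to 15019 was chosen after the data were seen.

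**Figure D4:**
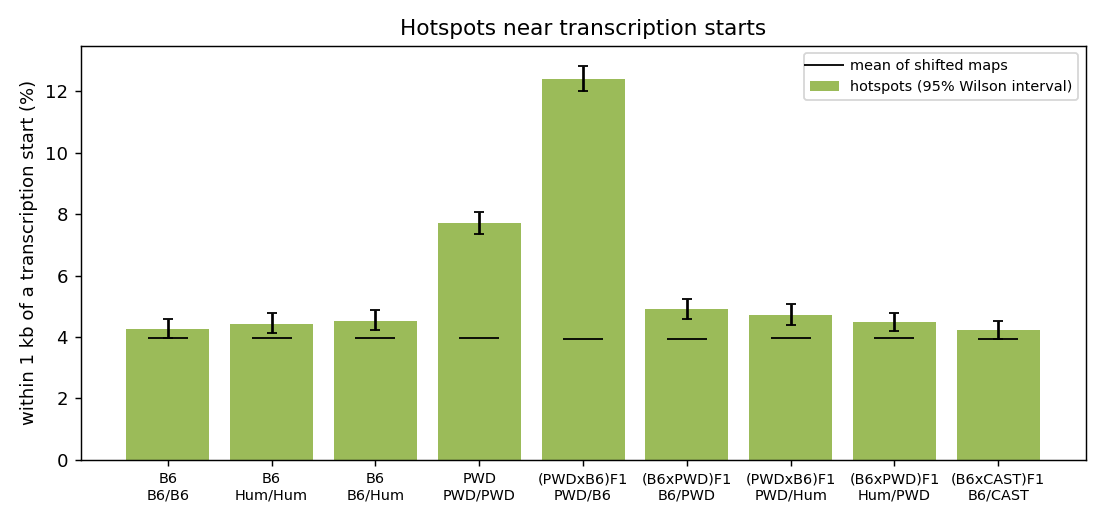
Share of autosomal hotspots within 1 kb of a protein-coding transcription start in each map, with the mean of maps shifted along the chromosomes.

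For the fixed list of meiotic recombination genes, the count of genes with a hotspot was highest in the PWD/PWD and infertile maps. Among 44 meiotic recombination genes 23 held a hotspot within 2000 bp in the PWD/PWD map and 23 in the infertile map, where 100 shifted maps gave 14.3 and 15.9 on average and 24 at most, so both counts lay within the shifted range. The other maps had from 11 (Hum/Hum) to 17 (Hum/PWD). Hsf2bp, a BRCA2 partner in meiosis, had a hotspot of heat 456.4 in the B6/B6 and 300.3 in the infertile map. Gm960, which encodes the SPO11 partner TOPOVIBL, had 446.4 in the infertile, 511.2 in the reciprocal and 25.7 in the PWD/PWD map. The axis gene Hormad2 had 392.8 in the PWD/PWD map. Prdm9 itself held 5 hotspots in the B6/B6 map, the hottest at 69.3, and none in the others. That map came from a library of other submitters, and the B6/Hum map, with the B6 allele too, had none there. The cause was not tested. Of 9 Sertoli cell genes 2 to 5 held a hotspot, of 7 Leydig cell genes 0 to 2, of 9 spermatid genes 0 to 2 and of 5 housekeeping genes 0 to 1.

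H3K4me3 at the starts of list genes was counted mainly in the infertile table, because a bin exists only where a hotspot was called. Its bins lay at the starts of 10 meiotic genes, all flagged as PRDM9-independent. Enrichment was 31.8 at Sycp3, which encodes a chromosome axis protein, 20.4 at Meiob, 16.2 at Syce1, 14.7 at Ccnb1ip1, 14.6 at Zcwpw1, 12.8 at Hormad2, 12.3 at Rnf212, 10.4 at Syce3, 10.1 at Mei4 and 7.73 at Gm960. The Sertoli and germ cell gene Dmrt1 had 18.4 and the X-linked housekeeping gene Hprt 31.6. The reciprocal table had bins at Zcwpw1 (4.29) and Hprt (11.4) only, and the rescue table at Ctcfl (2.78) only.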

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

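H3K4me3 sums in hotspot bins of the X chromosome stood on opposite sides of the autosomes in the F1 crosses. ChIP over input on X relative to autosomes was above 1 in both replicates of the infertile males (mean 1.05) and of the reciprocal males (mean 1.03), and below 1 in both replicates of the rescue males (mean 0.783), with n = 2 each. Infertile and rescue males are littermates and carry the same PWD X chromosome. The difference between infertile and rescue males had an exact p of 0.333, the smallest possible here, and reciprocal against rescue was not tested. With high-input bins kept, the reciprocal value turned to 0.990, and by median enrichment the infertile X ratio was 0.922, so the side of 1 depended on the measure.

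Hotspots matching neither homozygous map were flagged as well. Their ChIP over input relative to PWD-type hotspots was above 1 in both infertile replicates (mean 1.02) and below 1 in both reciprocal (mean 0.972) and rescue replicates (mean 0.801). The exact p was 0.333 for infertile against rescue and for infertile against reciprocal males, and reciprocal against rescue was not tested. With high-input bins kept, the rescue value turned to 1.03 and the infertile value was 1.01, so their order turned as well.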

How the results depend on the processing

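The 85 main values were recomputed under 249 alternatives. In 24 of them 1 of 2 H3K4me3 replicates was left out, which cannot leave 1 SD and shows nothing on stability. Of the other 225, 42 stayed within the 95% interval of the main value, or within 1 SD for H3K4me3 replicate values, 178 left it and 5 changed direction. Intervals of shares are narrow because they count very many hotspots, so small moves leave them. High-input bins kept and, for promoters only, the cut to the hottest 15019 hotspots were chosen after the data were seen. X hotspots could not be added to overlap, origin or F1 heat, and a minimum of 20 informative reads could not be applied to DMC1. A 500 bp limit for joining H3K4me3 bins was not run, because all centres were identical. No paired analysis was possible because no replicate was matched to another by animal or batch. Infertile and rescue males are described as littermates, but this names no pairs of replicates. Why values moved was not tested, except where the setting itself sets the value. Below, F1 values stand in the order infertile, reciprocal, rescue, Hum/PWD and, where given, CAST.

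Directions turned in 5 cases. With symmetry from 0.3 to 0.7 the heat ratio of asymmetric to symmetric hotspots was 0.960 in the rescue and 0.999 in the Hum/PWD map. The difference of the B6 share between PWD-type and Hum-type hotspots of the Hum/PWD map was -0.0197 by means against 0.009 by medians. With high-input bins kept, H3K4me3 on X relative to autosomes was 0.990 in reciprocal males, and neither-type relative to PWD-type hotspots was 1.03 in rescue males.

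A matching limit of 500 bp gave a B6/B6 and Hum/Hum overlap of 1.20% and a PWD/PWD and B6/B6 overlap of 1.22%, and 2000 bp gave 3.99% and 3.94%. With 2000 bp the Hum-only share of B6/Hum hotspots was 67.9%. PWD/PWD hotspots found in the F1 maps were 45.8, 34.0, 18.3 and 28.8% with 500 bp and 48.5, 36.0, 20.3 and 31.3% with 2000 bp. With 500 bp heat had a rho of 0.828 for infertile and rescue, 0.881 for reciprocal and Hum/PWD and 0.678 for B6/Hum and B6/B6 maps. With mm9 lists the Hum-only share was 67.8%.

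In the hotter 0.5 of every map the overlaps were 1.28% for B6/B6 in Hum/Hum and 1.18% for PWD/PWD in B6/B6, and the Hum-only share was 73.4%. Non-PWD hotspots among those matching a single map, 41.1, 45.2, 68.1 and 63.0% in the main analysis, were 43.1, 46.2, 72.5 and 66.3%. PWD/PWD hotspots found were 40.9, 27.6, 15.3 and 24.96%. The Spearman correlation of heat was 0.944 for infertile and reciprocal, 0.896 for rescue and Hum/PWD, 0.741 for infertile and rescue, 0.846 for reciprocal and Hum/PWD, 0.871 for B6/Hum and Hum/Hum and 0.516 for B6/Hum and B6/B6 maps. Symmetric shares were 43.1, 35.3, 53.6, 53.0 and 53.8%, and asymmetric to symmetric heat ratios 1.87, 1.78, 1.11, 1.12 and 1.48. The X to autosome heat ratio was 1.49. Enriched bins were 89.0% in B6/B6, 98.6% in Hum/Hum, 73.5% in reciprocal, 96.8% in infertile and 98.2% in rescue tables.

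With equal list lengths the non-PWD shares were 42.9, 46.2, 69.8 and 64.7%, and PWD/PWD hotspots found were 31.0% in infertile, 29.4% in reciprocal and 21.4% in Hum/PWD maps. By heat the non-PWD shares were 44.1, 47.6, 70.2 and 64.7% and the symmetric shares 34.3, 27.2, 53.6, 51.8 and 51.2%. By the authors' column the non-PWD shares were 43.7, 46.2 and 69.2%, and the B6 share differed between PWD-type and non-PWD-type hotspots by 0.319, 0.526 and 0.212. By means this difference was 0.213 in the reciprocal and 0.0427 in the rescue map.

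Symmetric shares were 47.2, 36.3, 47.8, 48.7 and 58.9% from 0.2 to 0.8 and 36.4, 26.9, 37.5, 38.9 and 48.7% from 0.3 to 0.7, as narrower limits must lower them. Heat ratios were 2.42, 1.93, 1.11, 1.17 and 2.67 with 0.2 and 0.8, and 1.93 in infertile, 1.61 in reciprocal and 2.04 in CAST maps with 0.3 and 0.7. By mean heat they were 2.57 in infertile, 1.29 in rescue, 1.39 in Hum/PWD and 2.36 in CAST maps, and the X to autosome ratio was 1.68.

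With p below 0.001 enriched bins were 51.3% in B6/B6, 78.5% in Hum/Hum, 30.4% in reciprocal, 68.3% in infertile and 74.9% in rescue tables. In p-passing bins only, the rho of heat with H3K4me3 was 0.601, 0.681, 0.412, 0.725 and 0.617 in the same order. Near-start shares over chance within 2500 bp were 1.19 in B6/B6, 1.28 in Hum/Hum, 1.28 in B6/Hum, 1.58 in PWD/PWD, 2.08 in infertile, 1.32 in rescue and 1.24 in Hum/PWD maps. In the hottest 15019 hotspots they were 1.53 in PWD/PWD and 1.98 in infertile maps.

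With high-input bins kept, non-PWD relative to PWD-type H3K4me3 was 1.15, 1.09 and 1.65 in infertile, reciprocal and rescue males. The share of ChIP fragments in PRDM9-independent bins was 79.8, 29.6 and 24.5%. Neither-type relative to PWD-type was 1.01 in infertile and 0.979 in reciprocal males, and X relative to autosomes was 0.807 in rescue males. Of the alternatives for values of lesser weight, such as the neither class and the H3K4me3 symmetric shares, 53 moved and 5 did not.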

Other observations

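Part of the hotspots found in neither homozygous map recurred in the CAST cross, mainly those on the PWD chromosome. Of 1975 neither-type hotspots of the infertile map with a B6 share below 0.1, 1015 or 51.4% (49.2 to 53.6%) were hotspots of the B6 by CAST map, where shifting gave 1.55%. In the CAST cross their median B6 share was 0.0505, and 71.5% lay below 0.1 and 0.299% above 0.9. Of the 2416 neither-type hotspots with a B6 share above 0.9, 17.5% (16.1 to 19.1%) were in the CAST map, with a median B6 share of 0.862. The reciprocal map gave 54.1% of 1864 and 18.8% of 2027. The sites near Tacr3 and Vgll3 were among these hot and one-sided sites. These are values of single libraries and were not tested.

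Promoter hotspots of the infertile map were found in 3 other maps less often than its hotspots as a whole. Of 2924 infertile-map hotspots near a transcription start, 34.2% were in the PWD/PWD map, 29.2% in the reciprocal and 9.44% in the rescue map, against 41.98, 72.3 and 22.0% of all its hotspots. Their median heat was 12.9, against 29.2 for the other infertile-map hotspots. Of the 1628 PWD/PWD hotspots near starts 60.3% were in the infertile map. Median H3K4me3 enrichment on X relative to autosomes was lower in both tables with a Hum allele, 0.544 in Hum/Hum and 0.670 in rescue males, than in B6/B6 (0.781), infertile (0.922) and reciprocal males (1.00). These differences were not tested.

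Among the tests below, those on equal list lengths, the reciprocal map, the side of the B6 share, groups of H3K4me3 enrichment and promoters among shared hotspots were chosen after their results had been seen. The others were written down first.

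The excess of promoter hotspots in the infertile map was not wholly explained by the length of its list, because in its hottest 15019 hotspots 7.84% still lay near a start against 6.04% in PWD/PWD and at most 4.71% in the other maps, although the cut lowered its ratio over chance from 3.15 to 1.98. The coldest of 3 equal heat groups reached 6.03% at most in the other maps, against 20.6% in the infertile and 11.8% in the PWD/PWD map. The groups were cut within each map and were not equally weak. The lowest heat was 4 in the infertile, 6.4 in the reciprocal and 13.7 in the rescue map. Weak hotspots as such are thus not excluded as a cause. PWD DNA read on the B6 reference could not be the sole cause, since the reciprocal map with the same genomes had 4.90%. Near starts 84.0% (82.5 to 85.4%) of infertile-map hotspots were symmetric, against 53.7% elsewhere, and within the coldest group 95.2% against 72.9%. In the coldest group of the reciprocal map, which had no such excess, the shares were 70.5 and 58.2%, in the rescue map 71.5 and 70.2%, in the Hum/PWD map 76.7 and 70.5% and in the CAST map 93.0 and 95.8%. The infertile values go with breaks at promoter H3K4me3 not placed by PRDM9, but symmetry near starts was not specific to that map. Background signal from both chromosomes would be symmetric too, so symmetry cannot tell it from such breaks. Breaks at these promoters remain a hypothesis from 1 library, and a different mix of testis cells in infertile males was not tested.

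The greater heat of asymmetric hotspots was not limited to the B6 side, where better mapping could raise it, because hotspots with a B6 share below 0.1 were at least 1.26 times as hot as symmetric ones in every F1 map. Symmetry taken from H3K4me3 reads still gave ratios of 2.14 in infertile, 2.04 in reciprocal and 1.28 in rescue males. The greater heat was thus not seen with DMC1 symmetry alone. Any background left in H3K4me3 reads could make weakly marked hotspots look symmetric too, so background from both chromosomes is not excluded. In bins with p below 0.05 outside PRDM9-independent bins, 5 equal groups of H3K4me3 enrichment gave a ratio of 1.31 at the lowest. At these hotspots the greater heat thus remained at like total enrichment of the bin. Total enrichment does not separate the 2 chromosomes, so marking of the bound chromosome was not held equal. Stronger marking there is not excluded. Slower repair of breaks whose partner chromosome lacks the site is a possible explanation that these maps cannot separate from break number. In the CAST map, without H3K4me3 data here, background could hold a part of the ratio of 3.61, which was not tested. The ratio fell to 1.48 in the hotter 0.5 of hotspots, but it fell in every F1 map. A cut on heat can narrow a ratio of heats by itself, so this fall does not measure background.

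The sharing of PWD/PWD hotspots with the B6 by CAST map did not look like material of one library in the other. Only 19.1% of the 2110 hottest PWD/PWD hotspots were found. Heat at the 2399 shared hotspots had a rho of 0.271. This rho decides nothing here, because the B6/B6 map, which shares an allele with the CAST cross, gave -0.0445 across 3359 shared hotspots. Common regions gave 1.81% after local shifts of 10 to 50 kb. Promoters could not be the cause, as 5.13% of the shared hotspots lay near a start, below the 7.71% of the whole PWD/PWD map. Similar binding sites of the PWD and CAST alleles are a possible explanation that a CAST/CAST map would test.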
